A study of Homo sapiens with 3 samples.

How the data were processed

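The series holds 3 arrays of human embryonic stem cells of the H3 MIXL1eGFP line, 1 for each of 3 groups: undifferentiated cells at day 0, and GFP-negative and GFP-positive cells sorted at day 3 of differentiation. Groups were taken from the sample titles. Per the labels' protocols, total RNA was isolated with Trizol, and biotinylated cRNA was made from 10 ug of it and hybridised to Affymetrix arrays. The deposited values are summarised probe set intensities on a linear scale, limited to between 20 and 20000, for 12698 probe sets. The method of summarisation, the normalization between arrays and the filter behind this choice of probe sets are not given in the sources used here. That the scale is linear was read from the values, whose medians lie between 256 and 338. The medians over these probe sets differ between the arrays, and whether the full arrays had been scaled to each other is not given in the sources used here. Values at 20 are lower limits of the scale, and a fold against such a value is given as a lower bound, the brighter intensity over 20.

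Probe sets were named through the platform annotation, and symbols were checked against a RefSeq gene table through Entrez IDs, which held 11740 of the 11751 named probe sets. Of all probe sets, 11181 had 1 gene symbol, 570 several and 947 none. Those with several or no symbols, and the 38 control probe sets, were left out of the gene table, which held 7839 genes. POU5F1 is named only on a probe set shared with its pseudogenes and is therefore not given a value. Where a gene had more than 1 probe set, as 2415 genes did, the one with the highest mean level over the 3 arrays was used, and for a named gene with a 2-fold difference the median of the others is stated where it points the opposite way or falls short of 2-fold.

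Intensities were transformed as log2 of the value plus 16, and the log2 difference of a pair of arrays was taken per gene. This pseudocount understates the difference of dim genes. The design allowed for either linear or log2 values, and this transformation was used because the values were linear. A gene was counted in a comparison where the higher of its values lay above the median of the gene-named probe sets of that array, which corresponds to an intensity of 316 at day 0, 342 in GFP-negative and 259 in GFP-positive cells. Genes with a difference of at least 1 (2-fold) were counted. Counts within gene lists do not use this filter. With 1 array per group there are no replicates, so no test was made and no p-value or error is given.

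For 25 lists of genes, fixed before the data were examined, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list outside the central 95% of random lists is described as standing apart, which describes these arrays and is not a test of the conditions. Of the 468 list members, 283 were measured. The genes named are MIXL1, the 12 genes with the largest positive and the 12 with the largest negative difference in each comparison among counted genes, leaving out uncharacterised symbols, and members of the lists, with at least the members of largest positive and negative difference in each comparison. This rule, the comparisons and the alternatives were also fixed before the data were examined, except for level-dependent normalization in 40 level bins and the exclusion of probe sets that can cross-hybridise, which were chosen after seeing the data.

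The alternatives were quantile normalization, median centring, no level filter or one at the 75th percentile, the mean over a gene's probe sets or the probe set with the median difference, probe sets with several genes kept, thresholds of 1.5-fold and 3-fold, and pseudocounts of 1 and 64. Gene lists were recomputed only with quantile normalization, median centring, level-dependent normalization, the mean over probe sets, both pseudocounts, the members above the level filter and the mean over members. The overlap of the day 3 differences was set beside 100 simulations of unchanged arrays against the shared day 0 array, with noise drawn from the spread between the day 3 arrays. The agreement of probe sets was measured on 1007 genes with at least a pair of probe sets above a mean log2 level of 8, with 95% intervals from 2000 resamples of genes, which cover the choice of genes only.

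The counting and the list step were tested on simulated data in which 200 genes were changed by 3-fold or 4-fold among 7839 genes. The simulated noise had a standard deviation of 0.2 in log2, and all probe sets of a changed gene moved together. The real arrays spread more: the log2 differences of a gene's probe sets lay a median of 0.74 apart for GFP-positive minus GFP-negative. The shares that follow therefore check the computation and are not error rates of these arrays. For GFP-positive minus GFP-negative, at least 98% of the genes raised or lowered were recovered, with 1 of 4545 unchanged genes counted, and 2 of 100 lists of unchanged genes stood apart. For GFP-positive minus day 0 at least 96% were recovered and 3 lists stood apart, and for GFP-negative minus day 0 at least 94% and 4 lists, the lowest shares being those of lowered genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.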

Results

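Gene expression was measured in 3 populations of human embryonic stem cells, with 1 Affymetrix array for each. The line, named H3 MIXL1eGFP in the labels, carries green fluorescent protein (GFP) in the locus of MIXL1, a homeobox gene active in the primitive streak, where mesoderm and endoderm arise. One population was undifferentiated, at day 0. The others were the GFP-negative and the GFP-positive cells sorted by flow cytometry at day 3 of a mesoderm and cardiac differentiation, begun with bone morphogenetic protein (BMP) 4 at 10 ng/mL, Activin A at 5 ng/mL and basic fibroblast growth factor (FGF) at 5 ng/mL. The labels give the GFP-negative cells as endoderm progenitors and the GFP-positive cells as mesoderm progenitors. The series was designed to find how the sorted day 3 populations differ in their transcriptomes.

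The deposited intensities lay between 20 and 20000, and their median was 315 at day 0, 338 in GFP-negative cells and 256 in GFP-positive cells. Of the 12698 probe sets, 95, 53 and 301 respectively stood at the lower limit of 20. Since each group has 1 array, no difference given here has a replicate check, no p-value or standard error can be had, and the number of arrays limits the precision of each value. Differences are log2 differences of intensity plus 16, and lists of genes are placed by the percentile of their median among 10000 random lists of matched level. Counts within lists take in all measured members, dim ones included.

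MIXL1 itself was read by 1 probe set, at an intensity of 33.7 at day 0, 43.8 in GFP-negative and 37.4 in GFP-positive cells. These values are close to the lower limit on every array, so the reporter's own gene gave no check of the sort. Where the dimmer value of a pair lies this low, the size of a difference is set in part by the lower limit and the pseudocount. Across 7839 genes the GFP-negative array correlated with day 0 at r = 0.792 and with the GFP-positive array at r = 0.784, whereas the GFP-positive array and day 0 correlated at r = 0.610. Genes are not independent replicates, and these correlations describe the arrays only.

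The control probe sets differed between the arrays. The 3' over 5' intensity ratio of the GAPDH control, a measure of how complete the labelled transcripts are, was 4.65 at day 0, 28.5 in GFP-negative and 173 in GFP-positive cells, where the 5' probe set read 38.9, so close to the lower limit that the size of this ratio is uncertain. For the ACTB control the ratio was 29.4, 134 and 9.93, and its 3' probe set read 960 in GFP-positive cells against 10724 in GFP-negative cells. Of 1007 genes with a pair of well-detected probe sets, the pair differed by at least 2-fold in 41.0% for GFP-positive minus GFP-negative and in 25.5% for GFP-negative minus day 0.

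**Figure D1:**
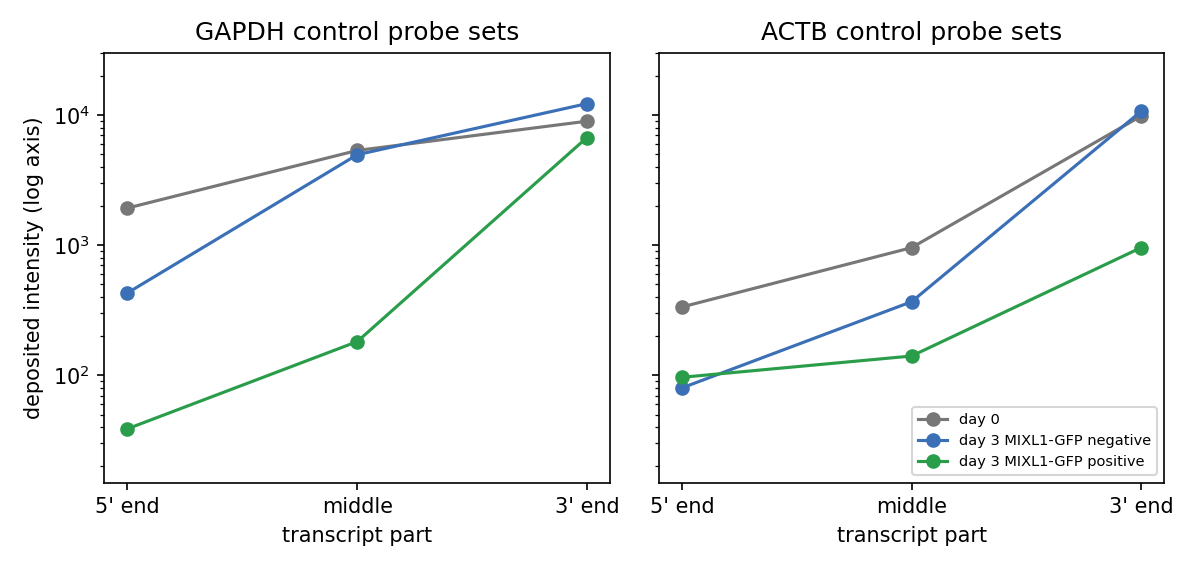
Deposited intensity (log axis) of the control probe sets at the 5' end, the middle and the 3' end of GAPDH (left) and ACTB (right), with 1 line per array. The middle GAPDH probe set read 5349 at day 0, 4959 in GFP-negative cells and 182 in GFP-positive cells.

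The GFP-positive and GFP-negative cells of day 3 were compared first, to show what the sort separated. Genes of early mesoderm were present in both populations, and as a group did not set them apart: over 16 measured genes the median difference was 0.0039, at percentile 82.3, and the alternatives lay between percentiles 79.8 and 97.1, the highest by the mean over members. PDGFRA, a receptor of paraxial and cardiac mesoderm, was higher in GFP-positive cells (intensity 2047 against 461), as was RSPO3, a WNT agonist (1360.5 against 264), while MSX1 (213 against 1301) and LEF1 (187 against 852) were lower. The endoderm regulator SOX17 was higher in GFP-positive cells by its main probe set (1906 against 356), and the chemokine receptor CXCR4 likewise (1028 against 290.4). Epithelial genes were lower in GFP-positive cells, with a median of -1.68 over 13 genes at percentile 0.02, and so were the reference housekeeping genes, with a median of -1.59 over 11 genes at percentile 0.08.

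Of the 8 measured primitive streak genes, none was at least 2-fold higher in GFP-positive cells and 2 were lower. EOMES, a T-box factor of the streak, had an intensity of 4810.2 in GFP-negative and 1169 in GFP-positive cells (difference -2.03), and the ligand gene NODAL read 576 and 127. TBXT (brachyury) and MESP1, a regulator of the earliest cardiac mesoderm, differed by less than 2-fold, with differences of -0.69 and 0.64. The list median was -0.38, at percentile 44.3. In the early mesoderm list, HAS2 was higher by its main probe set (difference 1.24), lower by its other one (-1.58) and at -0.17 by their mean, and APLNR, the apelin receptor gene, differed by 0.50. Of 8 cardiac genes, 7 were within 2-fold, among them GATA6 (-0.06), HAND1 (-0.33) and ISL1 (0.03), and ACTC1 was lower (-1.61); the list lay at percentile 66.1.

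In the definitive endoderm list, 4 of 10 genes were at least 2-fold higher in GFP-positive cells and none was lower, with a median of 0.16 at percentile 90.5 and a mean of 0.59 at percentile 99.9. These were SOX17 (2.37), CXCR4 (1.77), APOA2 (178 against 55.8) and FLRT3 (1.31), and 5 of the 10, APOA2 among them, were below the level filter. The other SOX17 probe set pointed the opposite way, with a difference of -0.99, and the other FLRT3 probe set gave 0.32. CER1, an antagonist of Nodal, BMP and WNT, differed by -0.52. The endothelial and blood list had only 3 measured genes and a median of 1.15, at percentile 99.5: SOX7 was higher (2.03), TAL1 was higher (193 against 77.9, below the level filter), and KDR differed by -0.40. The trophoblast and amnion list had a median of -1.13 over 7 genes at percentile 4.14, with TFAP2A (-2.28), GATA3 (-1.96) and TFAP2C (-1.13) lower in GFP-positive cells and EPAS1 at 32.8 against 122. The other GATA3 probe sets had a median difference of 0.04.

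The BMP targets split within the list. All of the ID genes, which encode inhibitors of helix-loop-helix factors, were lower in GFP-positive cells, at 30.0 against 2320.2 for ID1 and with differences of -2.50 for ID3, -2.28 for ID4 and -1.93 for ID2. BMP4 was lower as well (-2.86), whereas BMP2 (1.78), SMAD6 (1.35), SMAD9 (1.07) and TBX3 (1.04) were higher. The other probe set of BMP2 gave -0.88 and those of TBX3 a median of 0.06. Over 14 genes, 4 were higher and 6 lower, and the median of -0.56 lay at percentile 22.4 (2.54 with the mean over probe sets and 2.67 with the mean over members). Of 10 WNT genes, LGR5 (2.06), NKD1 (1.53) and WNT5A (1.03) were higher, LEF1 (-2.10) and AXIN2 (-1.03) were lower, and the median was 0.19 at percentile 87.5. The other probe set of WNT5A gave -0.32 and that of NKD1 0.44. The 9 Nodal and Activin genes had a median of 0.00064 at percentile 72.1, with NODAL, GDF3 (-2.00) and SKIL (-1.08 by its main and -0.23 by its other probe set) lower. The 15 FGF and ERK targets had a median of -0.80 at percentile 6.77, with ETV1 (33.3 against 251), SPRY4 (-1.84) and ETV4 (-1.48) lower and SPRED1 (0.73) the highest. ACVR1B (0.91) was the highest Nodal and Activin gene. The NOTCH list had a median of 0.55 at percentile 98.3 with 8 of its 9 genes within 2-fold, HEYL (0.82) the highest. Its mean was -0.25, opposite in sign, since HES1 stood at 20 in GFP-positive and 633 in GFP-negative cells. The other HES1 probe set differed by 0.31, and the NOTCH list was at percentile 59.7 over its members above the level filter.

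Epithelial genes at least 2-fold lower in GFP-positive cells numbered 8 of 13, and none was higher. CLDN6 (37.4 against 633, and 0.30 by its other probe set), RAB25 (-2.78), KRT19 (-2.02) and CDH3 (-1.68) were lower, whereas CDH1, which encodes E-cadherin, differed by -0.95, EPCAM by -0.33 and CRB3 by -0.02. Core pluripotency genes had a median of -0.88 over 17 genes, at percentile 2.48, which became 8.53 with the mean over each gene's probe sets and 3.19 with a pseudocount of 1. SALL4 (-3.69), SOX2 (-2.81), DNMT3B (-2.10), LIN28A (-1.93) and NANOG (-1.49) were lower, and ZFP42 (1.01) was higher, though the other probe sets of SOX2 and NANOG gave -0.35 and -0.81. The immediate early genes had a median of -1.16 over 11 genes at percentile 1.27, with CCN2 (-3.12), CCN1 (-2.91) and MYC (-2.13) lower and IER3 (0.76) the highest. Beside these groups stood the ribosomal protein genes, 11 of 19 of which were lower (median -1.29, percentile 0.02; RPS9, at -4.67, the lowest), and the housekeeping genes, 8 of 11 of which were lower, among them EEF1A1 (-2.90), GAPDH (-2.82) and YWHAZ (-2.36). The other EEF1A1 probe set gave -0.56, and those of YWHAZ had a median of 0.14; the highest members were RPL37 (0.72) and B2M (0.17). The 3' over 5' ratio of the GAPDH control was higher in GFP-positive than in GFP-negative cells (173 against 28.5), and that of ACTB was lower (9.93 against 134). The ACTB ratio fell with its 3' reading (960 against 10724), while its 5' readings were low on both arrays (96.6 and 80.0). It therefore does not show more complete ACTB transcripts in GFP-positive cells. Glycolysis genes had a median of -0.75 at percentile 5.28 (1.98 with the mean over probe sets, 2.49 with the mean over members), with HK2 (1.10) higher, and 5 neuroectoderm genes one of -0.67 at percentile 24.6, with OTX2 (0.82) the highest. Mesenchymal and matrix genes did not stand apart, with a median of -0.24 over 15 genes at percentile 53.6: ZEB1 (210.1 against 41.7, and 0.37 by its other probe set) and COL5A1 (1.60) were higher, COL1A1 (-2.76) and FN1 (-2.27) lower.

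Among genes outside the lists, the largest differences towards GFP-positive cells were those of the folate receptor gene FOLR1 (2130.5 against 36.4), the mitochondrially encoded ND6 (3.67) and the receptor gene EGFR (3.58), followed by PIK3R1 (2.60), SF3A2 (2.54), PCDH17 (2.51), FREM1 (2.46), CHRNA3 (2.43), TMEFF2 (2.41) and ERBB4 (273 against 40.8). The other probe sets of PIK3R1 and PCDH17 had median differences of -0.19 and -0.36, and those of FREM1 and TMEFF2 gave 0.24 and 0.98. Towards GFP-negative cells they were those of APELA, which encodes a peptide ligand of the apelin receptor (-5.71), and the actin-binding profilin gene PFN1, which was at least 78.8-fold lower in GFP-positive cells. NUCKS1 (-5.04), the tetraspanin gene CD9 (-4.87), the galanin gene GAL (-4.85) and the claudin gene CLDN10 (-4.84) were lower too. CCAR1, TGS1, BPTF, RO60 and LSM2 read between 1018 and 1618 in GFP-negative cells and between 21.4 and 39.5, close to the lower limit, in GFP-positive cells. The other probe sets of CCAR1 and TGS1 differed by 0.12 and -0.13, and the other probe sets of BPTF had a median difference of 0.61. Of the 13 other probe sets of the 12 genes lowest in GFP-positive cells, 6 were also at least 2-fold lower, and of the 9 other probe sets of the 12 highest, 2 were at least 2-fold higher.

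In all, 364 of 5360 genes were at least 2-fold higher and 1310 at least 2-fold lower in GFP-positive cells. This split depends on the scaling between arrays: quantile normalization gave 946 higher and 873 lower, median centring 993 and 889, and level-dependent normalization 1013 and 908. The median of all genes was -0.28 as deposited and 0.14, 0.10 and 0.12 after these scalings, and the medians of the primitive streak, cardiac and mesenchymal lists turned from negative to positive with them. The counts also rest on the probe set used. Other probe sets of the 364 higher genes had the same sign in 57.7% and passed 2-fold in 14.8%. For the 1310 lower genes these shares were 77.9% and 48.9%.

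**Figure D2:**
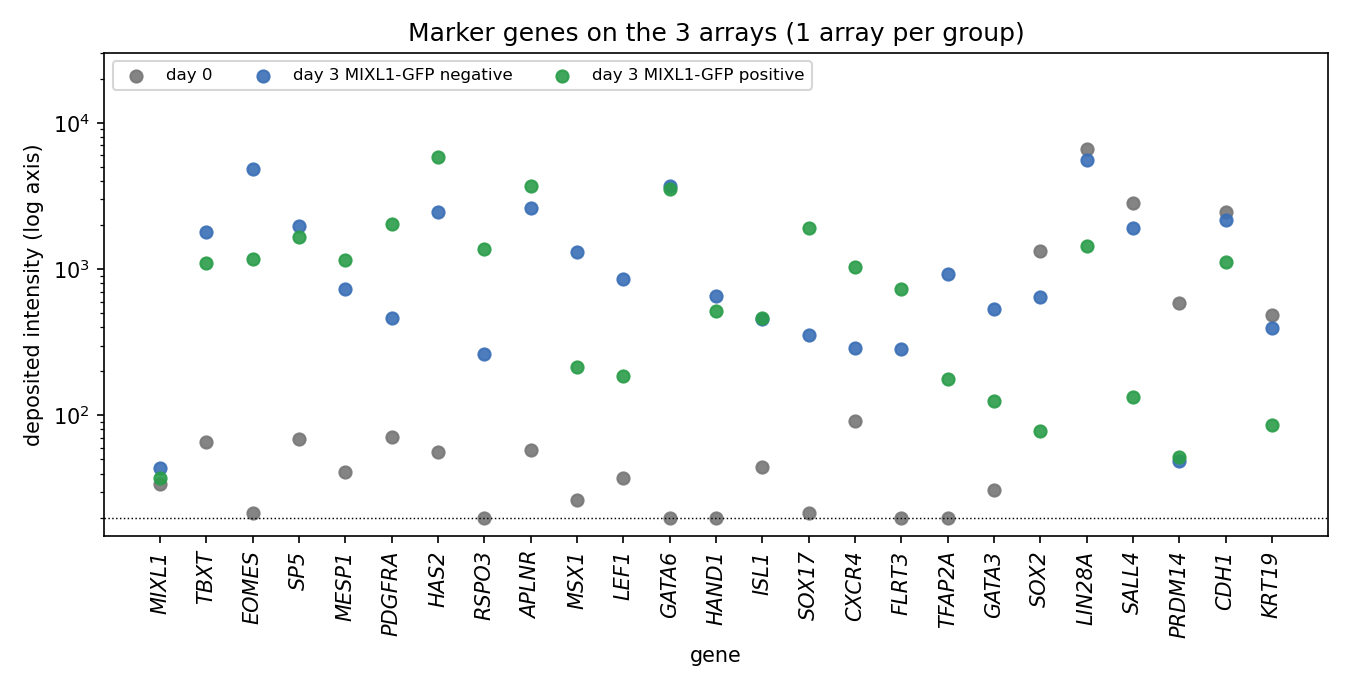
Deposited intensity (log axis) of marker genes on the day 0, GFP-negative and GFP-positive arrays, with 1 point per array and a dotted line at the lower limit of 20. EOMES stood at 21.6, 4810.2 and 1169, and MIXL1 stood between 33.7 and 43.8.

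GFP-positive cells of day 3 were next compared with the undifferentiated cells of day 0. Genes of the primitive streak, early mesoderm and endoderm were higher than at day 0, and pluripotency genes were lower, as were the housekeeping genes (median -1.27) on this array with its GAPDH 3' over 5' ratio of 173 against 4.65. The early mesoderm list had a median of 2.45, with 14 of 16 genes at least 2-fold higher, and the primitive streak list a median of 2.43, with 5 of 8 higher; both lay at percentile 100. The zinc finger gene GATA6, used in both cardiac and endoderm formation, was at least 177-fold higher, and the WNT antagonist gene DKK1 read 3397 against 21.5. The pluripotency genes had a median of -1.50 at percentile 0, with SALL4 at 134 against 2836 and SOX2 at 78.6 against 1328, while ZFP42 (1.77) was higher.

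Among early mesoderm genes, HAS2, a hyaluronan synthase gene, read 5853 against 56.1 at day 0, APLNR 3705 against 57.9, PDGFRA 2047 against 70.5 and MESP1 1145 against 40.7. RSPO3 was at least 68.0-fold higher. KDR differed by -0.23. In the streak list EOMES read 1169 against 21.6, SP5 differed by 4.30, TBXT by 3.78 and NODAL by -0.85. The cardiac list had a median of 1.34 over 8 genes at percentile 99.2 (97.3 with a pseudocount of 64), with HAND1 (at least 26.0-fold) and ISL1 (463 against 44.1) higher and ACTC1 (-1.03) lower. In the definitive endoderm list 8 of 10 genes were higher (median 2.34, percentile 100), including SOX17 (1906 against 21.5), FLRT3 (at least 36.5-fold) and CXCR4 (3.27), and FOXA3 (-0.86) was the lowest; the other SOX17 probe set gave 1.78. The trophoblast and amnion list had a median of 1.60 over 7 genes at percentile 99.7, with TFAP2A (at least 8.88-fold) and GATA3 (126 against 30.8) higher and TFAP2C (-0.86) the lowest. The mesenchymal and matrix list had a median of 1.25 at percentile 99.9, with COL5A1 (3.68) and CDH11 (at least 23.1-fold) higher and COL1A1 (-3.44) lower, and the other CDH11 probe set gave 0.26. Of 3 endothelial and blood genes, SOX7 was at least 22.0-fold higher, and the list lay at percentile 81.4. Neuroectoderm genes had a median of -0.58 over 5 genes at percentile 24.98, with ZIC2 (2.29) and OTX2 (1.56) higher and SOX2 (-3.83) and SOX3 (-1.17) lower.

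Of the signalling lists, those of WNT and BMP stood apart. The WNT list had a median of 1.92 and the BMP target list a median of 2.22, both at percentile 100. WNT5A (2179 against 27.2) and BMP2 (2703 against 23.2) were higher by each of their probe sets from day 0 values close to the lower limit, AXIN2 differed by -0.93, and LGR5, a receptor for R-spondins, was at least 66.0-fold higher. ID1 was lower than at day 0 (-3.74), at 30.0 against 599. LEFTY1, a Nodal antagonist gene, was lower (-2.97), SMAD7 was higher (2.79), and the Nodal and Activin list had a median of 0.61 at percentile 86.0. The FGF and ERK list lay at percentile 57.6, with DUSP6 (3.10) higher by its main probe set (median of its others -0.42) and ETV1 (33.3 against 318) lower, and the NOTCH list at percentile 46.4, with DLL3 (2.37) higher and NRARP (-2.09) lower. Outside the lists MCC (2691 against 40.2), the neurotensin gene NTS (5.52) and RHOBTB3 (5.08) were among the highest, and NUCKS1 (-6.20), APELA (-5.82) and JADE1 (-5.67) among the lowest. With them were CCAR1, BPTF, PWP1, CDC42BPA, MAD2L2, PWAR6, MTF2, SRRM2 and ESF1, which read between 1722 and 2734 at day 0 and between 21.1 and 41.6, close to the lower limit, in GFP-positive cells. The other probe sets of CCAR1 and ESF1 were higher than at day 0, by 1.31 and 2.11, and those of RHOBTB3 and BPTF had medians of 0.19 and 0.27.

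Epithelial genes (median -1.63, percentile 0.01) and glycolysis genes (median -0.82, percentile 1) were lower than at day 0, with KRT8 (43.8 against 392), CLDN7 (-2.38), CLDN6 (37.4 against 692, and -0.50 by its other probe set), ENO2 (-4.03) and ENO1 (-2.88) among them; CRB3 (-0.17) and SLC2A1 (0.74) were the highest members. Housekeeping genes were lower too, with a median of -1.27 at percentile 0.15, EEF1A1 (-2.96) the lowest and B2M (1.30) the highest, beside 3' over 5' ratios of 173 against 4.65 for GAPDH and 9.93 against 29.4 for ACTB. The ACTB ratio fell with its 3' reading, which was 960 against 9846 at day 0. The immediate early list had a median of -0.997 at percentile 2.62 and a mean at percentile 0.63, with IER3 (1.76) higher and CCN1 (-4.02) lower, and the ribosomal protein list a median of -0.30 at percentile 10.7 and a mean at percentile 0.79, with RPLP2 (1.21) higher and RPS9 (-3.66) lower. In this comparison 1326 of 5625 genes were at least 2-fold higher and 1405 lower; median centring gave 1828 and 1125, so the share of higher genes among them was 48.6% as deposited and 61.9% after centring. The median of all genes was -0.03 as deposited and 0.24 after centring. Other probe sets of the 1326 higher genes had the same sign in 54.2% and passed 2-fold in 32.2%. For the 1405 lower genes these shares were 84.5% and 65.8%.

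GFP-negative cells of day 3 were last compared with the undifferentiated cells. They too had higher levels of primitive streak and early mesoderm genes, while the pluripotency list was closer to its day 0 level. EOMES read 4810.2 against 21.6, TBXT 1792 against 66.0, and GATA6 was at least 184-fold higher. The early mesoderm median was 2.92, with 15 of 16 genes at least 2-fold higher, and the primitive streak median was 2.66, with 6 of 8 higher; both lay at percentile 100. The pluripotency median was -0.26 at percentile 0.82, or 6.09 over the members above the level filter: PRDM14 (-3.21), FOXD3 (29.4 against 150.1) and SOX2 (-1.02) were lower, whereas GDF3 (1.97) and SFRP2 (1.21) were higher and LIN28A (-0.26) and NANOG (0.71) were within 2-fold. The other SOX2 probe set gave -3.50, close to its -3.85 in GFP-positive cells, and the other NANOG probe set gave -0.90.

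Early mesoderm genes with the largest differences were APLNR (5.16) and HAS2 (5.10), MSX1 read 1301 against 26.3 and LEF1 852 against 37.1, and KDR differed by 0.17. The cardiac list lay at percentile 99.8, with HAND1 (at least 32.9-fold) and ISL1 (453 against 44.1) higher and MYOCD at 22.2 against 20. In the definitive endoderm list 7 of 10 genes were higher (median 1.78, percentile 100), with SOX17 at 356 against 21.5 and CXCR4 at 290.4 against 91.9 and FOXA3 (-0.55) the lowest. Of 7 trophoblast and amnion genes, 6 were higher (median 2.97, percentile 100): TFAP2A was at least 46.1-fold higher, GATA3 (536 against 30.8), GATA2 (1.30) and EPAS1 (122 against 39.3) were higher too, and TFAP2C differed by 0.27. The mesenchymal and matrix list had a median of 1.73 at percentile 100, with COL5A2 (3.10) and FN1 (1.80) higher, the vimentin gene VIM at 890 against 304, CDH11 at least 27.5-fold higher by its main probe set (0.01 by the other) and COL1A1 (-0.68) the lowest. Epithelial genes lay at -0.15, percentile 5.49, with 12 of 13 within 2-fold, CLDN7 (-1.53) lower and RAB25 (0.98) the highest. The neuroectoderm list lay at percentile 40.6, with ZIC2 (1.65) the highest, and the endothelial and blood list at percentile 42.3, with SOX7 at least 4.78-fold higher and TAL1 (-0.23) the lowest.

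All 14 measured BMP targets were at least 2-fold higher than at day 0, with a median of 2.46 at percentile 100. MSX1, BMP2 (777 against 23.2), ID2 (3.93), ID3 (3.15), ID4 (2.53) and ID1 (1.92) were among them, and NOG (64.5 against 23.1) was the least raised. The WNT list had a median of 2.12 at percentile 100, with SP5 (4.53) higher, DKK1 at 2350.1 and WNT5A at 1057 against day 0 values of 21.5 and 27.2, and NKD2 (-0.01) the lowest. Nodal and Activin genes had a median of 1.27 at percentile 99.8 and a mean of 0.85 at percentile 95.9, with SMAD7 (2.39) and NODAL (1.19) higher and LEFTY1 (-3.03) lower. The FGF and ERK list lay at percentile 57.7 by its median and 98.4 by its mean, with DUSP6 (3.15) and SPRY4 (2.23) higher and ETV4 (-0.34) the lowest. NOTCH genes lay at percentile 12.5, with HES1 (2.78) and DLL3 (1.63) higher and LFNG (-1.43), HEY2 (-1.35) and NRARP (-1.12) lower. Glycolysis genes had a median of -0.23 at percentile 0.47, with ENO2 (-2.46) and PFKM (-1.58) lower and SLC2A1 (0.56) the highest. Housekeeping genes (0.16, percentile 8.96) and immediate early genes (0.32, percentile 50.9) did not stand apart, and ribosomal protein genes (0.69, percentile 92.7) did so after quantile normalization (percentile 97.8). Their highest and lowest members as deposited were HPRT1 (1.20) and SDHA (-0.58), ZFP36 (1.06) and ATF3 (-2.07), and RPL11 (2.40) and RPL37 (-0.42). The housekeeping gene PPIA stood at the upper limit of 20000, so its 1.14 is a lower bound and it may lie above HPRT1. The 3' over 5' ratio was 28.5 against 4.65 at day 0 for GAPDH and 134 against 29.4 for ACTB.

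Outside the lists NTS (5.18) was among the highest, and so was MAGEA6 (4.41), whose probe set cannot be assumed to separate it from the similar MAGEA genes. The chaperonin genes HSPD1 (-5.19) and CCT2 (-3.21) were among the lowest, with CLC (23.2 against 923), the tryptophan-degrading enzyme gene IDO1 (73.6 against 1415), KDM4A (-3.94), EIF5A (43.7 against 809), CDC42BPA (-3.52), PHACTR2 (-3.44 by its main and -0.51 by its other probe set), SYT6 (-3.39), MBP (-3.32) and POM121C (-3.24). In all, 1114 of 5196 genes were at least 2-fold higher and 521 lower. Quantile normalization gave 875 and 722 and level-dependent normalization 626 and 823, so the direction of the split depended on the scaling. The median of all genes was 0.32 as deposited, and 0.14 and 0.06 after these scalings. Other probe sets of the 1114 higher genes had the same sign in 67.8% and passed 2-fold in 36.4%. For the 521 lower genes these shares were 78.2% and 46.8%.

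**Figure D3:**
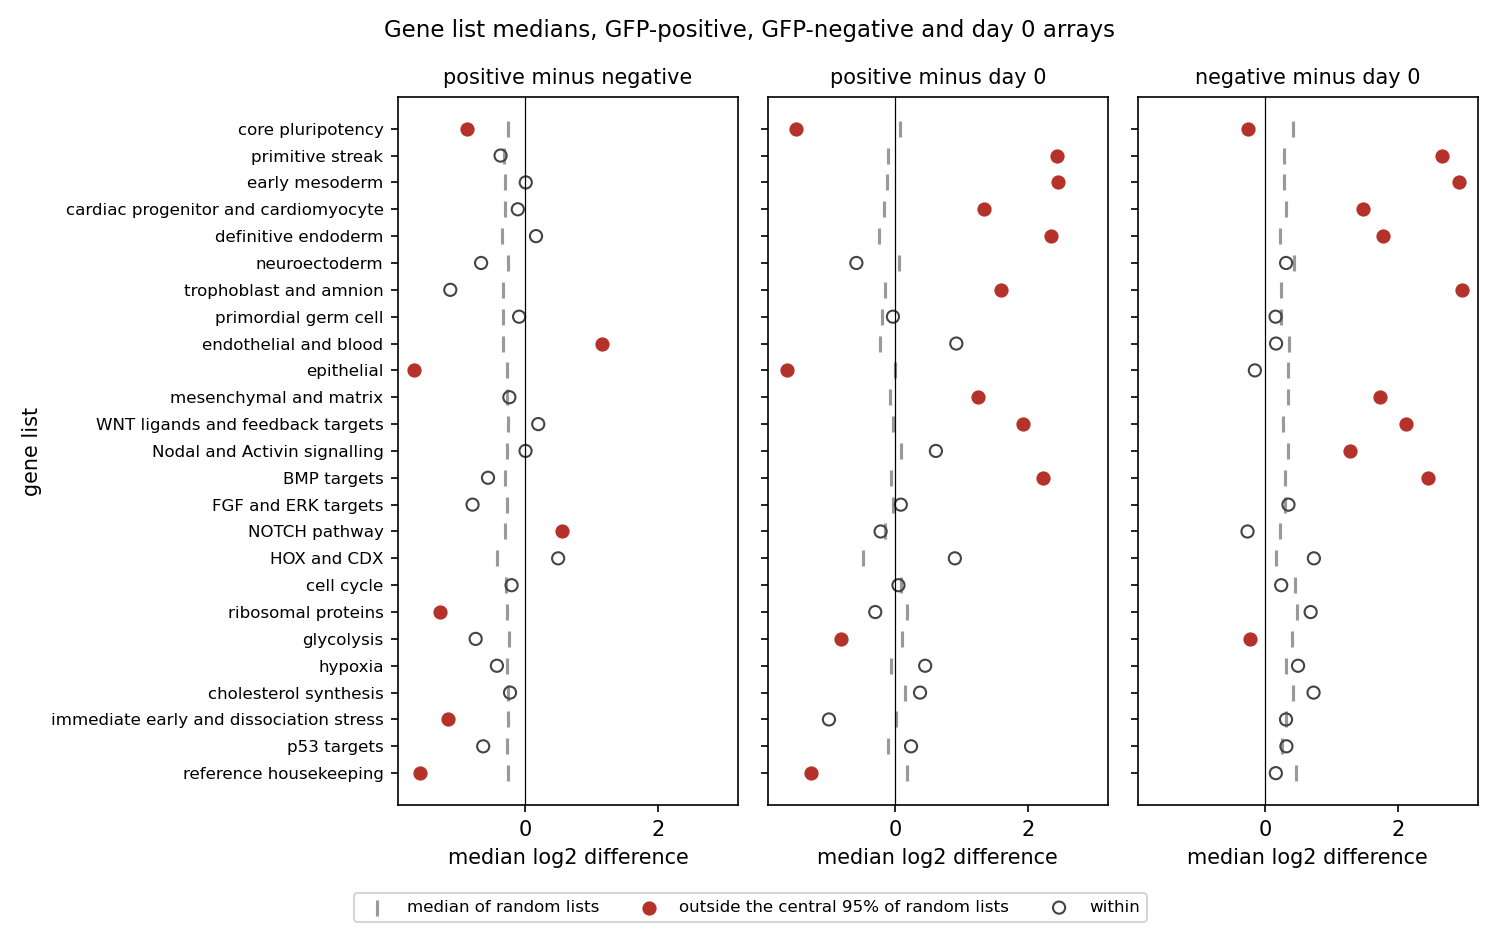
Median log2 difference of the 25 gene lists in the 3 comparisons, with filled points for lists outside the central 95% of random lists and a grey mark at the median of the random lists of matched level. Early mesoderm lay at 2.45 and 2.92 against day 0 on the GFP-positive and GFP-negative arrays and at 0.0039 between them.

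The day 3 populations shared many of their differences from day 0. Of 4903 genes, 964 were at least 2-fold higher in GFP-positive and 952 in GFP-negative cells, and 596 were higher in both, among them GATA6, DKK1 and APLNR. Independent lists of these sizes would share 187, and simulated unchanged arrays set against the same day 0 array shared a median of 242. Lower genes numbered 1403 and 521, with 420 in both, among them PRDM14 and LEFTY1, beside 149 for independent lists and 348.5 in the simulation, whose highest value was 390.0. Both comparisons use the single day 0 array, and part of the excess may come from it. The simulated arrays had no shift from day 0, whereas the median of all genes was -0.03 in GFP-positive and 0.32 in GFP-negative cells. Their noise, taken from the day 3 arrays, also holds real differences between these. The sizes of the simulated lists were not matched to the real ones. The simulated counts therefore do not measure how far the sharing exceeds noise.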

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

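All tests of explanations in this part were chosen after the results were seen. The control probe sets, which enter no comparison of genes, departed from day 0 in several places, as ratios or as readings. The 3' over 5' ratio of GAPDH was 28.5 in GFP-negative and 173 in GFP-positive cells, against 4.65 at day 0, and that of ACTB was 134 in GFP-negative cells, against 29.4. The bacterial hybridisation controls were 2.89 times their day 0 intensity in GFP-positive cells (median of 18 probe sets) and 0.511 times in GFP-negative cells. Of the probe sets without a gene name, 76 of 422 above the level filter were at least 2-fold higher than day 0 in GFP-negative and 91 of 466 in GFP-positive cells, shares below those of named genes (21.4% and 23.6%).

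Of 4903 genes, 41 were at least 2-fold from day 0 in opposite directions on the day 3 arrays, a difference that was not tested. Of these 41, 39 were higher in GFP-negative and lower in GFP-positive cells. This split was taken on the deposited values only. It was not repeated under the other scalings, with which the split between the day 3 arrays turned. Members of the gene lists among them were ID1 (1.92 in GFP-negative, -3.74 in GFP-positive cells), CCN2 (1.04 and -2.08), PPIA (1.14 and -1.04), RPL18 (1.42 and -1.34) and RPS9 (1.01 and -3.66). PPIA stood at the upper limit of 20000 in GFP-negative cells, so 1.14 is a lower bound, and the other RPL18 probe set gave 0.10 and 0.51. EGFR and ND6 were lower in GFP-negative and higher in GFP-positive cells, with the other EGFR probe set at 0.96 in the latter.

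The first pattern weighed is that, as deposited, more genes were lower (1310) than higher (364) in GFP-positive against GFP-negative cells, housekeeping and ribosomal protein genes among them, though quantile normalization gave 873 lower and 946 higher. Scalings that align the bulk of genes did not remove the lower housekeeping genes, whose median stayed at -1.20 or below under 3 of them. A shift common to all genes would also not place them at percentile 0.08 of random lists. These scalings moved the median of all genes only from -0.28 to between 0.10 and 0.14, and they take most genes as the reference. The bacterial hybridisation controls had a median of 3685 in GFP-positive and 637 in GFP-negative cells. A scaling of another kind on the GFP-positive array therefore stays open. Larger technical spread on the GFP-positive array was weighed too. The log2 differences of a gene's probe sets correlated less for GFP-positive minus GFP-negative than for GFP-negative minus day 0. The difference in correlation was -0.192 (interval -0.284 to -0.102). Pairs at least 2-fold apart made up 41.0% against 25.5%, and 45.0% for GFP-positive minus day 0. Spread alone has no direction, so it would not by itself make more genes lower than higher. A smaller true difference between the day 3 arrays would also lower this correlation. It would not lower that of GFP-positive minus day 0, which was 0.321 (interval 0.261 to 0.382). For GFP-negative minus day 0 the correlation was 0.431 (interval 0.359 to 0.499). These last intervals overlap, and no interval of their difference was taken. The part of technical spread in this pattern is therefore not decided. Loss of signal away from the 3' end stays open, since GFP-positive over GFP-negative intensity was 0.549 at the 3' end, 0.0366 in the middle and 0.0904 at the 5' end of GAPDH but 0.0895, 0.383 and 1.21 for ACTB, with 5' readings near background (38.9 for GAPDH and 96.6 for ACTB in GFP-positive cells), and both 3' over 5' ratios rose from day 0 to GFP-negative cells while the housekeeping median was 0.16. A difference between the sorted cells themselves stays open too and was not tested.

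The second pattern is that epithelial and core pluripotency genes were lower in GFP-positive than in GFP-negative cells. If they shared only the drop of the housekeeping genes, their medians would not lie further below 0 than the housekeeping median. The epithelial median was -0.10 from it (interval -1.02 to 1.23) and the pluripotency median 0.71 from it (interval -0.65 to 1.98). These intervals come from resampling the genes of each list on this pair of arrays and cover the choice of genes only. They reach to both sides of 0 and are too wide to decide. The drop of housekeeping genes and a difference tied to the sort therefore cannot be told apart for either list. A biological difference between GFP-positive and GFP-negative cells stays open, as untested.

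The third pattern is that SOX17, CXCR4, APOA2 and FLRT3 of the endoderm list were higher in GFP-positive cells, while the labels name the GFP-negative cells as endoderm progenitors. An exchange of the day 3 labels could give this, but the early mesoderm list lay at percentile 82.3 in GFP-positive minus GFP-negative cells (79.8 to 97.1 under the alternatives), on the side that goes against an exchange but within the central 95% of random lists, single genes went both ways (PDGFRA 2.11 and RSPO3 2.30, EOMES -2.03 and NODAL -2.04), and MIXL1 was too close to the lower limit to decide. The choice of probe set could also matter, since the other SOX17 probe set gave -0.99, whereas that of FLRT3 gave 0.32 and CXCR4 and APOA2 had no other. Neither explanation can be told apart from a difference between the sorted cells, which was not tested.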

How the results depend on the processing

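Level-dependent normalization and the exclusion of cross-hybridising probe sets were chosen after seeing the data. No paired analysis was possible because each group has 1 array and no test was made. Leaving out the GFP-positive array, whose GAPDH ratio was the highest, leaves only the comparison of GFP-negative cells with day 0. The controls of that pair differ too. Its 18S ribosomal RNA controls had medians of 190.4 in GFP-negative cells and 10334 at day 0, and its ACTB 3' over 5' ratios were 134 and 29.4. Values at the lower limit of 20 bound the folds of dim genes. Of the 30 list medians outside the central 95% of random lists, 25 stayed outside on the same side under each of the 8 alternatives run for lists, and of the 45 within, 37 stayed within; the endothelial and HOX lists had 7, with too few members above the level filter. Where a cause is not given, the cause was not tested.

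For GFP-positive minus GFP-negative, the count of higher genes (364) became 946 by quantile normalization, 993 by median centring and 1013 by level-dependent normalization, and that of lower genes (1310) became 873 by quantile normalization. The 75th percentile filter, which admits fewer genes, gave 216 higher and 714 lower, a 1.5-fold threshold 1067 and 1966, and a 3-fold threshold 83 and 717. For GFP-positive minus day 0 the filter gave 828 and 780, the 3-fold threshold 597 and 840, and the 1.5-fold threshold 2132 higher. For GFP-negative minus day 0 level-dependent normalization gave 626 and 823, the filter 629 and 290.0, the 1.5-fold threshold 2080 and 1014, and the 3-fold threshold 379 and 182. Genes higher than day 0 on both day 3 arrays numbered 206 at 3-fold and 915 without a filter, and lower ones 136 at 3-fold. Over genes above the median mean level, the correlations were 0.674 (GFP-positive with GFP-negative), 0.451 (GFP-positive with day 0) and 0.735 (GFP-negative with day 0).

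Lists that crossed the percentile bounds in GFP-positive minus GFP-negative were core pluripotency (-0.81 with the mean over probe sets and -0.89 with pseudocount 1, both inside the bounds), definitive endoderm (1.31 over members above the level filter and mean 0.59, both outside), trophoblast and amnion (-0.63 by quantile normalization and -0.94 with pseudocount 64, both outside), NOTCH (0.90 by level-dependent normalization and 0.20 over members above the filter, both inside, and a mean of -0.25), glycolysis (-0.99 with the mean over probe sets and mean -0.88, both outside) and p53 targets (-1.36 with the mean over probe sets, outside). For GFP-positive minus day 0 they were cardiac (0.82 with pseudocount 64, inside), ribosomal proteins (mean -0.60, outside) and immediate early genes (-1.73 with the mean over probe sets and mean -1.21, both outside). For GFP-negative minus day 0 they were core pluripotency (-0.0049 over members above the filter, inside), Nodal and Activin (mean 0.85, inside), FGF and ERK (0.94 with the mean over probe sets and mean 0.83, both outside) and ribosomal proteins (0.37 by quantile normalization and mean 0.76, both outside).

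Of 567 differences of named genes, 523 kept their side of 2-fold with the mean over probe sets and 509 with quantile normalization. Many named genes had no other probe set, so their mean equals the value used and could not change side. The 523 includes these differences, so its share of 567 overstates the stability of genes with several probe sets. With the mean over probe sets 8 turned: HAS2 (-0.17) and RHOBTB3 (-0.28) for GFP-positive minus GFP-negative, HES1, positive minus day 0 (0.040), ACVR1B, positive minus day 0 (-0.43), TOP2A, positive minus day 0 (-1.78), TOP2A, negative minus day 0 (-0.062), ESF1, negative minus day 0 (0.26), and SKIL, negative minus day 0 (-0.075).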

Other observations

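The lists given here, fixed before the data were examined, had medians within the central 95% of random lists in every comparison as deposited. The 24 cell cycle genes had medians of -0.21 for GFP-positive minus GFP-negative, 0.05 for GFP-positive minus day 0 and 0.24 for GFP-negative minus day 0, at percentiles 64.4, 45.5 and 13.4, and the first and last changed sign under other scalings. CDK1 and PCNA were higher than day 0 in both day 3 populations (CDK1 at 4982 and 4422 against 1752, PCNA at 5356 and 5303 against 1571), while MKI67 was higher in GFP-positive cells by its main probe set (1.76; the other gave 0.57). TOP2A was higher by its main probe set (1.85 in GFP-negative and 1.70 in GFP-positive cells) and lower by its other one (-1.97 and -5.26). MCM3 (-2.11), AURKB (-1.78) and MCM7 (-1.19) were lower than day 0 in GFP-positive cells. By the probe sets used, 5 of the 24 were higher there, TOP2A among them, and 3 lower. In GFP-positive against GFP-negative cells AURKB was the lowest (-2.29) and MKI67 the highest (2.09; the other gave 0.50), and MCM4 was the lowest of GFP-negative cells against day 0 (-0.81). The 13 cholesterol synthesis genes lay at percentiles 52.7, 69.4 and 90.2. Within that list HMGCS1, SC5D, MSMO1 and INSIG1 (by its main probe set; the others had medians of -0.45 in GFP-positive and 0.41 in GFP-negative cells) were at least 2-fold higher than day 0 on both day 3 arrays, with SC5D at 2298 in GFP-positive and 2469 in GFP-negative against 661 at day 0. EBP (-2.55), SQLE (-2.12) and PMVK (149.7 against 316) were lower than day 0 in GFP-positive cells, where NSDHL was the highest (1.82; its other probe set gave -0.21); in GFP-negative cells PMVK was the lowest, at 150.1. Between the day 3 arrays EBP was the lowest (-3.02) and NSDHL the highest (1.08; the other gave -0.60).

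The 12 hypoxia genes lay at percentiles 35.1, 82.4 and 71.8 in the same order of comparisons. LOX, which encodes an enzyme that cross-links collagen, was at least 12.8-fold higher in GFP-positive cells than at day 0, and read 30.7 in GFP-negative cells. BNIP3 read 4378 in GFP-positive, 1586 in GFP-negative and 1261 in day 0 cells (its other probe set differed by 0.19 between the day 3 arrays), whereas PDK1 was higher in GFP-negative cells (1166 against 561 in GFP-positive cells, and 256 at day 0). ADM (-1.80) was the lowest in GFP-positive against GFP-negative cells, P4HA1 (-1.69) in GFP-positive cells against day 0 and BNIP3L (-0.18) in GFP-negative cells against day 0. The 7 measured p53 targets lay at percentiles 23.8 (1.3 with the mean over probe sets), 68.0 and 57.3, the 6 germ cell genes at 68.7, 58.4 and 42.9, and the 4 HOX genes, all below the level filter, at 93.9, 88.1 and 77.3. Of the p53 targets, MDM2 was higher in GFP-positive than in GFP-negative cells (1.25; its other probe set gave 0.94) and TP53I3 lower (-1.62); against day 0, MDM2 (1.71) and PMAIP1 (-1.46) were the ends in GFP-positive and ZMAT3 (0.89) and PMAIP1 (-0.0062) in GFP-negative cells. The germ cell gene DND1 was lower than day 0 in both populations (-2.25 in GFP-positive, -1.37 in GFP-negative cells, where its other probe set gave -0.99), and HOXB3, a gene of anterior to posterior patterning, read 24.0 at day 0, 68.8 in GFP-negative and 114 in GFP-positive cells. HOXB2 read 138 in GFP-positive and 64.8 in GFP-negative cells, HOXD1 69.4 and 186 with 45.5 at day 0, and HOXB6 39.4 and 26.8 with 25.5 at day 0. In the germ cell list SOX17 was the highest in every comparison and TFAP2C the lowest between the day 3 arrays.

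The 18S ribosomal RNA control probe sets had a median of 10334 at day 0, 190.4 in GFP-negative and 1771 in GFP-positive cells. The Dap, Lys, Phe and Thr control probe sets had medians of 224, 124 and 24.2, and 4 of the 8 stood at the lower limit in GFP-positive cells.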
